A study of Mus musculus with 14 samples.

How the data were processed

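RNA was prepared with a micro-scale column kit from sorted fetal thymic ETP of C57BL/6 mice, and libraries were made with a kit of the SMART-Seq type. The labels give the library source as genomic although the protocol describes RNA. Per the submitters' processing notes, bcl2fastq, STAR and HOMER were used with the mm9 build, without versions, roles or counting parameters, and strandedness is not stated. The deposited tables hold expected counts, without normalisation, for 25094 RefSeq transcripts each, 1 per gene, in steps of 0.5, and 29.6% and 29.3% of the values in experiments 1 and 2 are not whole. They were rounded to whole numbers, whereas the tests had been planned for raw counts. Gene symbols came from a reference annotation of a later build and were used as names only, matching 24977 and 24971 transcript IDs, and the 117 and 123 others kept their IDs. Coordinates came from the files. The tables share 25076 genes, 1712 of them counted on different transcripts. All per-sample columns were used. Totals ran from 20146286 to 31182294 counts per library. Reads of near-identical copies, such as Akr1c12 and Akr1c13, Klrc1 and its relatives, or Ifit3 and Ifit3b, are of uncertain origin. Tdg and Tdg-ps2 have overlapping coordinates and are 1 locus counted in 2 rows.

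Each experiment was tested in 1 model of all its groups with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, genes kept by filterByExpr (minimum count 10, minimum total 15), robust quasi-likelihood dispersions, quasi-likelihood F-tests (two-sided) and an adjusted p (Benjamini-Hochberg) of 0.05 as the threshold. The 9 comparisons were dKO versus Cont, dKO_NICD versus dKO and versus Cont, each mutant of experiment 2 versus B6, N1Edel_E47KO versus E47KO and versus N1Edel, and the interaction, that is the change from N1Edel to N1Edel_E47KO minus the change from B6 to E47KO. The common biological coefficient of variation was 0.297 in experiment 1 and 0.256 in experiment 2. CPM use the TMM library sizes. A fold against a group at 0 is a lower bound from a floor of 3 counts over the group, and floors cover counting error only. SE are those of the fitted log2 fold changes.

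The comparisons, 23 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The lists were E and Id proteins, Notch pathway targets, T-lineage specification, stem and progenitor, ILC2 and ILC precursor, ILC3 and lymphoid tissue inducer, NK and ILC1, myeloid, mast cell and basophil, B-lineage, dendritic cell, gamma-delta T cell, CD4 CD8 double-positive thymocyte, erythroid, thymic stroma, S phase, G2 and M phase, p53 targets and BCL2 family, immediate early and heat shock, interferon response, cytokine and homing receptors, glycolysis, and ribosomal proteins. They were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation, camera refers its statistic to the residual degrees of freedom, 3 in experiment 1 and 4 in experiment 2. The adjusted p covers the lists of 1 comparison. A list was called at an adjusted p under 0.05 with the preset correlation. Some genes belong to more than 1 list.

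The rule named, for each comparison, the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 10 CPM in the higher group and every library separated, leaving out predicted, antisense and small RNA genes. It added up to 4 members with the smallest p from each list with at least 5 tested, 18 genes of E-protein and Notch biology in every comparison, the 10 shared genes with the largest smaller change for each overlap, and the 8 smallest p for the interaction. Of the genes that the rule names, the text describes a part. Among these, genes whose call held under the alternatives were preferred, so the share of held calls among described genes is no estimate for all calls. Dct, the 45S rRNA, the Y-chromosome genes, and Gzmb in dKO_NICD versus dKO fall outside the rule and were chosen after their values were seen.

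The alternatives were size factors by the DESeq2 method, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, only the groups compared, all 14 libraries in 1 fit, and each library left out in turn. Where 1 library is left in a group, it is assumed to vary like those of the other groups. Overlaps were compared with the number that independent lists would share and, where comparisons share libraries, with 20 data sets simulated with unchanged or replaced groups (seed 1). A test on simulated data changed 200 genes at 5 CPM or more per comparison, by 2-fold and 4-fold for 100 each. The edgeR test recovered 52% and 92% of these in dKO versus Cont, 45% and 94% in dKO_NICD versus dKO, 50% and 88% in dKO_NICD versus Cont, 43% and 95% in E47KO versus B6, and 36% and 92% in N1Edel versus B6. It recovered 41% and 94% in N1Edel_E47KO versus B6, 41% and 90% in N1Edel_E47KO versus E47KO, 42% and 94% in N1Edel_E47KO versus N1Edel, and 1% and 72% in the interaction, with 1 to 14 calls among unchanged genes. On the same simulated data DESeq2 recovered more, for example 66% and 96% in dKO versus Cont, but had 34 to 65 calls among unchanged genes. Marker lists for the closing section were written after the first results, as lists of 15 melanoblast genes (7 seen before), 16 genes of mature macrophages and neutrophils (4 seen before) and 15 dendritic cell genes (0 seen before). Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.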

Results

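Gene expression was measured by bulk RNA-seq in early T progenitors (ETP), the KIT-high CD44+CD25- cells that are the most immature T-lineage precursors of the thymus, sorted from the fetal thymus of gene-targeted mice. The sorting gate also excluded cells positive for CD4, CD8 or any of a panel of markers of mature T, B, myeloid, erythroid, NK and dendritic cells. The 14 libraries fell into 7 groups of 2 libraries, in 2 experiments that were deposited as separate count tables and were normalised and tested separately. Experiment 1 held control ETP (Cont), ETP with floxed Tcf3 and Tcf12 and Il7r-Cre (dKO), and ETP with the same alleles and the active intracellular domain of NOTCH1 (NICD) from the Rosa26 locus (dKO_NICD). Tcf3 and Tcf12 encode E2A and HEB, basic helix-loop-helix transcription factors of the E-protein family, whose DNA binding is blocked by the Id proteins. Experiment 2 held wild-type ETP (B6), ETP without E47, an isoform of E2A (E47KO), ETP homozygous for a deletion that the labels name N1En (N1Edel), and ETP with both changes (N1Edel_E47KO). The series addresses how E-protein activity and Notch signalling set the ETP transcriptome. Total counts were 22362700 and 24943562 in the Cont libraries, 26211964 and 28496977 in dKO and 25563936 and 24491156 in dKO_NICD. They were 25356750 and 22849038 in B6, 31182294 and 21337277 in E47KO, 28128566 and 20146286 in N1Edel, and 22299434 and 27992934 in N1Edel_E47KO. The labels do not state that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Levels below are normalised counts (CPM, counts scaled to a common library total), as the mean ± SD with n = 2 libraries unless given per library, and fold changes are log2 values ± SE.

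The targeted genes were examined first, in each library. Tcf3 (chromosome 10, 79871910 to 79896398, mm9) was at 147 and 174 CPM in Cont, 9.95 and 17.1 CPM in dKO and 60.9 and 59.2 CPM in dKO_NICD. Tcf12 (chromosome 9, 71692059 to 71959626) was at 232 and 213 CPM in Cont, 9.26 and 9.58 CPM in dKO and 16.9 and 15.6 CPM in dKO_NICD. In experiment 2, Tcf3 was at 247 and 244 CPM in B6, 75.8 and 77.9 CPM in E47KO, 267 and 269 CPM in N1Edel and 97.9 and 72.0 CPM in N1Edel_E47KO. The counts are per gene, so they do not separate E47 from the other E2A isoform. Notch1 (chromosome 2, 26313422 to 26359342) was at 483 and 439 CPM in Cont, 114 and 117 CPM in dKO and 225 and 271 CPM in dKO_NICD, where reads of the transgene, if any, would be counted with the gene. It was at 362 and 337 CPM in B6, 56.0 and 49.4 CPM in E47KO, 25.1 and 25.7 CPM in N1Edel and 36.6 and 37.4 CPM in N1Edel_E47KO. Every library of a targeted group lay below every control library of its experiment for the gene concerned. The libraries also differed in the genes of the Y chromosome, which summed to 221 and 127 CPM in Cont, 0 and 0.035 CPM in dKO, 228 and 197 CPM in dKO_NICD, 62.3 and 66.8 CPM in B6, 223 and 173 CPM in E47KO, 0 and 0 CPM in N1Edel, and 86.8 and 249.8 CPM in N1Edel_E47KO. The share of male cells therefore differs between the groups, and genes of the Y chromosome are not named among the changes below. All 4 tested were called in dKO versus Cont, dKO_NICD versus dKO, N1Edel versus B6 and N1Edel_E47KO versus N1Edel. Effects of sex were not separated from those of genotype in any comparison. Xist, an RNA of female cells, was at 0.045 and 40.9 CPM in Cont and 18.9 and 0.071 CPM in N1Edel_E47KO. This argues against technical repeats of 1 sample in these 2 groups.

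**Figure D1:**
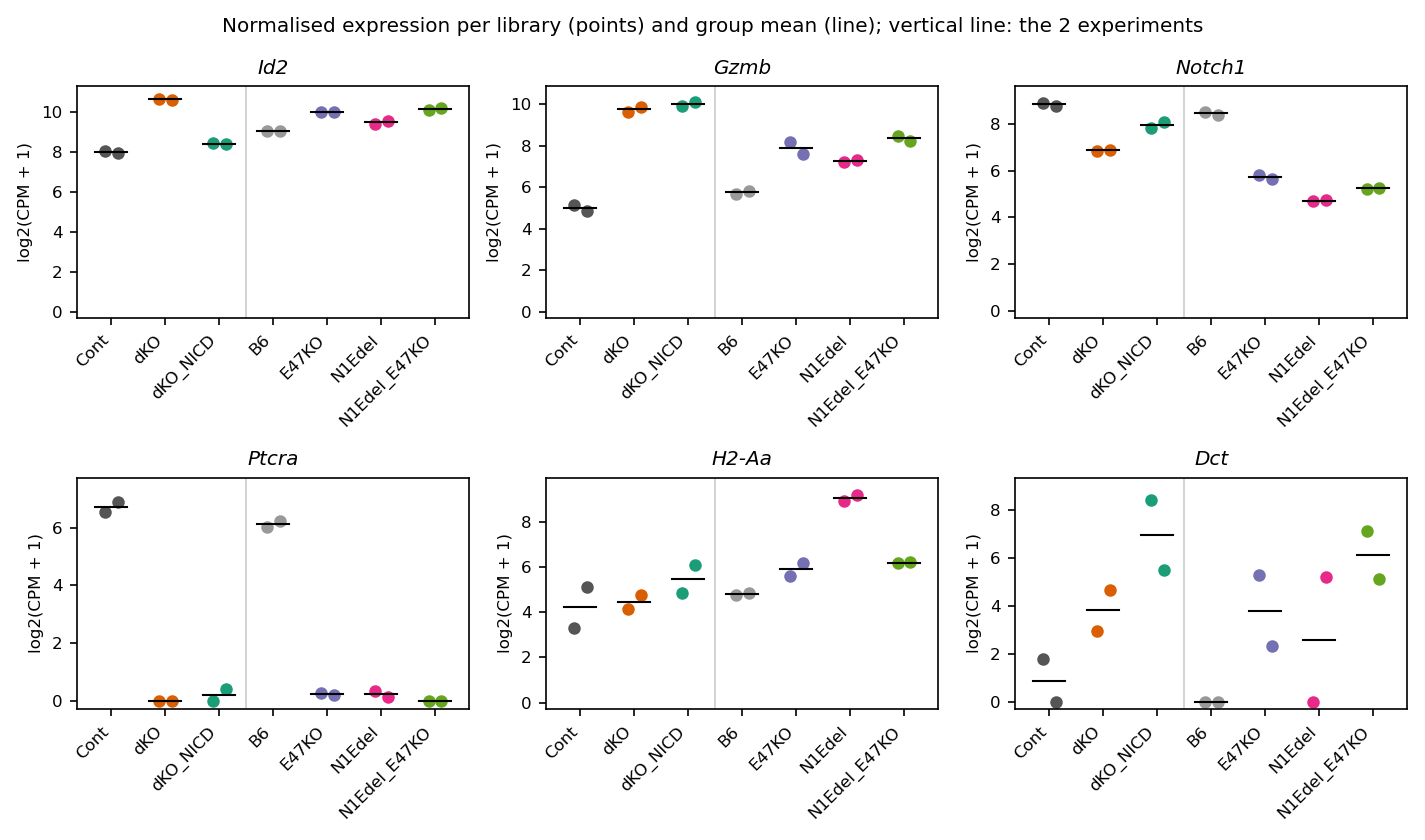
Level of 6 genes in each of the 14 libraries, as log2(CPM + 1), with a dot per library, a line at the mean of the log values of each group, and experiments 1 and 2 normalised separately. Ptcra was at 105 ± 18.4 CPM in Cont and at 0.159 ± 0.225 CPM in dKO_NICD, and H2-Aa at 535 ± 59.5 CPM in N1Edel against 26.7 ± 1.17 CPM in B6.

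Deletion of Tcf3 and Tcf12 was examined by comparing dKO with Cont. The sorted dKO fraction had higher levels of natural killer (NK) and innate lymphoid cell (ILC) transcripts and lower levels of many T-lineage transcripts. Bulk counts, here and in the comparisons below, do not separate expression by ETP from that by other cells in the sort. Y-chromosome genes were at 0 and 0.035 CPM in dKO and 221 and 127 CPM in Cont. Effects of sex therefore cannot be told apart from those of the deletion. Id2, which encodes an inhibitor of E proteins that ILC need, rose from 252 ± 8.98 to 1578 ± 38.9 CPM (2.65 ± 0.08, adjusted p = 1.07e-04). Gzmb, a protease of cytotoxic granules, rose from 31.1 ± 4.12 to 866 ± 101 CPM (4.80 ± 0.16, adjusted p = 1.54e-04). So did Tbx21, the transcription factor T-bet (4.90 ± 0.25), Klrb1c, the NK1.1 receptor (4.98 ± 0.29), and Klrc1, the receptor NKG2A (5.44 ± 0.33). Ptcra, the invariant chain of the pre-T cell receptor, was at 105 ± 18.4 CPM in Cont and at 0 in both dKO libraries, at least 1829.8-fold lower (adjusted p = 0.00180). Rag1, the recombinase of antigen receptor genes, fell from 201 ± 35.4 to 0.293 ± 0.299 CPM (-9.35 ± 0.50, adjusted p = 4.95e-04). The Notch receptor genes Notch1 and Notch3 fell as well (-1.99 ± 0.12 and -4.27 ± 0.25). Of 14137 genes tested, 2554 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1452 of them higher and 1102 lower in dKO. Without Cont replicate 1 the count was 596, without Cont replicate 2 it was 436, and without dKO replicate 1 it was 1575.

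Among the gene lists, 3 of innate lymphocytes were higher in dKO with the preset correlation of camera. NK and ILC1 genes had 19 higher and 1 lower of 20 tested (19 and 1 adjusted over the list alone). Adjusted p was 1.83e-11 by camera and 0.127 with an estimated correlation. ILC2 and ILC precursor genes had 13 higher and 0 lower of 23 tested (17 and 0 adjusted over the list alone). Adjusted p was 1.71e-10 by camera and 0.127 with an estimated correlation. The called members included Il2rb, a chain of the receptors for IL-2 and IL-15 (3.12 ± 0.12) and the chemokine receptor Cxcr6 (2.48 ± 0.16). Genes of ILC3 and lymphoid tissue inducers had 6 higher and 1 lower of 13 tested (7 and 1 adjusted over the list alone). Adjusted p was 0.00100 by camera and 0.127 with an estimated correlation. Ltb and Lta, which encode lymphotoxins, were both higher (1.89 ± 0.12 and 3.23 ± 0.28). Interferon response genes had 17 higher and 0 lower of 19 tested (19 and 0 adjusted over the list alone). Adjusted p was 1.83e-11 by camera and 0.397 with an estimated correlation. These included Irf7, a transcription factor of the antiviral response (3.44 ± 0.32, adjusted p = 0.00236), and Oas1a, an enzyme of antiviral defence (3.01 ± 0.33, adjusted p = 0.00362). Notch pathway targets had 1 higher and 8 lower of 15 tested (1 and 9 adjusted over the list alone). Adjusted p was 2.44e-04 by camera and 0.127 with an estimated correlation. Dtx1 and Hes1 were not called (0.13 ± 0.23, adjusted p = 0.750 and -0.15 ± 0.75, adjusted p = 0.922), and their signs turned without dKO replicate 1 (-0.28 for Dtx1) and without Cont replicate 2 (0.61 for Hes1). T-lineage specification genes had 5 higher and 12 lower of 25 tested (5 and 13 adjusted over the list alone). Adjusted p was 0.0269 by camera and 0.397 with an estimated correlation. Lef1 and Runx1, transcription factors used in early T cells, fell (-1.45 ± 0.11 and -1.06 ± 0.09). Cd28, a costimulatory receptor, rose (2.75 ± 0.23, adjusted p = 0.00170). Gata3 and Bcl11b, both needed for T-lineage commitment, were not called (0.48 ± 0.20, adjusted p = 0.151 and -0.24 ± 0.37, adjusted p = 0.704), and Bcl11b was at 0.008 without dKO replicate 2.

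Metabolic and receptor genes of dKO also differed from Cont. Glycolysis genes had 7 higher and 1 lower of 17 tested (7 and 1 adjusted over the list alone). Adjusted p was 0.00100 by camera and 0.623 with an estimated correlation. The higher ones included Slc16a3, a lactate transporter, and Pfkp, a phosphofructokinase (1.95 ± 0.12 and 1.56 ± 0.10). Cytokine and homing receptors had 14 higher and 2 lower of 23 tested (14 and 2 adjusted over the list alone). Adjusted p was 8.52e-05 by camera and 0.127 with an estimated correlation. Sell, the homing receptor L-selectin, fell from 672 ± 86.8 to 80.8 ± 2.71 CPM (-3.06 ± 0.12, adjusted p = 2.16e-04). The p53 target and BCL2 family genes had 8 higher and 0 lower of 17 tested (9 and 0 adjusted over the list alone). Adjusted p was 4.58e-04 by camera and 0.127 with an estimated correlation. Immediate early and heat shock genes had 5 higher and 1 lower of 18 tested (5 and 1 adjusted over the list alone). Adjusted p was 0.0472 by camera and 0.397 with an estimated correlation. Ribosomal protein genes had 0 higher and 2 lower of 84 tested (0 and 1 adjusted over the list alone). Adjusted p was 4.58e-04 by camera and 0.704 with an estimated correlation. The other 12 lists did not pass camera's test. Stem and progenitor genes had 4 higher and 2 lower of 20 (4 and 5 adjusted over the list alone, camera adjusted p = 0.322). Mast cell and basophil genes had 5 higher and 1 lower of 11 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0587). Dendritic cell genes had 5 higher and 1 lower of 13 (5 and 1 adjusted over the list alone, camera adjusted p = 0.126). Myeloid genes had 2 higher and 1 lower of 21 (2 and 1 adjusted over the list alone, camera adjusted p = 0.539). B-lineage genes had 1 higher and 3 lower of 10 (2 and 3 adjusted over the list alone, camera adjusted p = 0.377). Gamma-delta T cell genes had 1 higher and 3 lower of 13 (4 and 3 adjusted over the list alone, camera adjusted p = 0.718). Double-positive thymocyte genes had 2 higher and 2 lower of 11 (3 and 3 adjusted over the list alone, camera adjusted p = 0.539). Erythroid genes had 1 higher and 0 lower of 14 (1 and 0 adjusted over the list alone, camera adjusted p = 0.0777). Thymic stroma genes had 1 higher and 0 lower of 11 (1 and 0 adjusted over the list alone, camera adjusted p = 0.539). S phase genes had 1 higher and 2 lower of 21 (1 and 2 adjusted over the list alone, camera adjusted p = 0.126). G2 and M phase genes had 0 higher and 0 lower of 22 (0 and 0 adjusted over the list alone, camera adjusted p = 0.718). E and Id protein genes had 1 higher and 2 lower of 6 (1 and 2 adjusted over the list alone, camera adjusted p = 0.382). Dct, an enzyme of melanin synthesis, was at 6.89 and 24.3 CPM in the dKO libraries and 2.46 and 0 CPM in the Cont libraries. With an estimated correlation, no list passed in any comparison other than N1Edel versus B6, where 3 did.

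**Figure D2:**
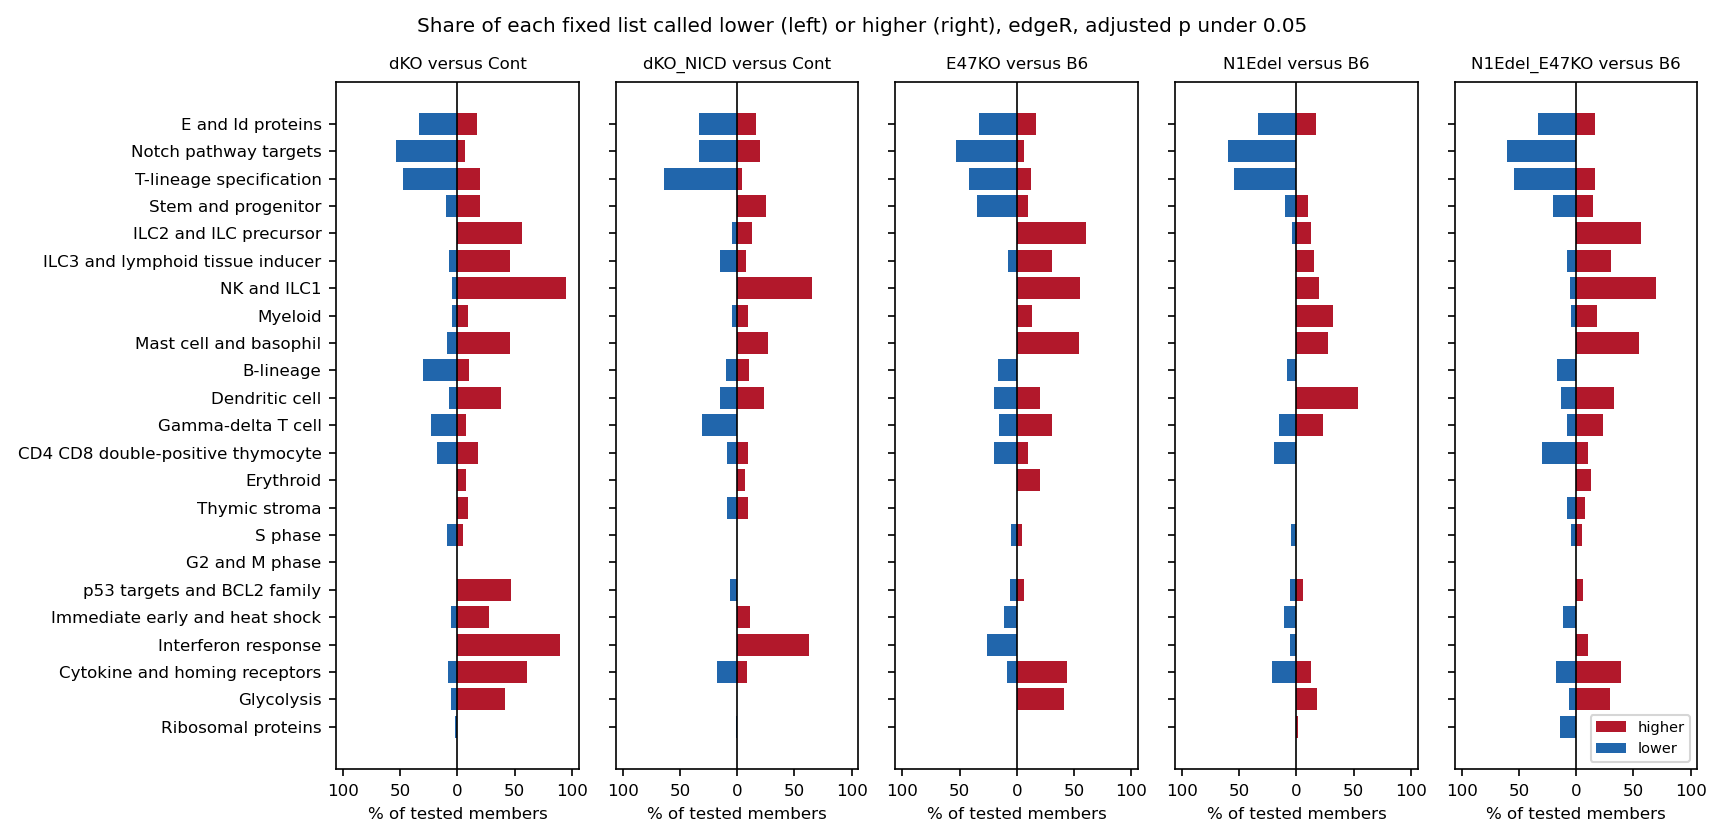
Share of the tested members of each of the 23 gene lists that were called lower (left of 0) or higher (right of 0) at an adjusted p of 0.05, for 5 comparisons with the control group of their own experiment, each experiment normalised separately. In dKO versus Cont, 19 of 20 NK and ILC1 genes were called higher, and in N1Edel versus B6 the counts were 8 of 15 for dendritic cell genes.

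The dKO_NICD group was compared with dKO, from which it differs by label in active NOTCH1, and also in the targeted gene Tcf3 (60.0 ± 1.18 CPM against 13.5 ± 5.03 CPM). The groups differ in Y-chromosome genes as well (228 and 197 CPM in dKO_NICD, 0 and 0.035 CPM in dKO). Effects of sex cannot be told apart from those of NICD in this comparison. The dKO_NICD ETP had lower levels of many of the innate lymphoid transcripts and higher levels of Notch targets and progenitor genes. Id2 fell from 1578 ± 38.9 to 338 ± 9.74 CPM (-2.22 ± 0.07, adjusted p = 5.92e-04). Il2rb, Cxcr6 and the costimulatory receptor gene Icos fell (-2.66 ± 0.12, -3.54 ± 0.17 and -2.26 ± 0.16). Rorc, the transcription factor of ILC3, fell from 31.9 ± 5.05 to 1.06 ± 0.523 CPM (-4.91 ± 0.38, adjusted p = 0.00360). Heyl and Dtx1, 2 targets of Notch signalling, rose (4.84 ± 0.25 and 1.78 ± 0.24), while Hes1, another, did not pass (-0.67 ± 0.76, adjusted p = 0.626, and 0.08 without dKO_NICD replicate 2). Cd34, Mef2c and Hhex, genes of stem and progenitor cells, were higher by 2.51 ± 0.19, 2.11 ± 0.14 and 1.53 ± 0.18. Of 14137 genes, 1129 passed the threshold, 505 higher and 624 lower in dKO_NICD. With all 14 libraries in 1 fit, 1020 were higher and 947 lower, and in a fit of only the groups compared 87 and 210. Notch1 was higher (1.10 ± 0.11), where counts per gene do not separate the transgene, as was Tcf3 (2.15 ± 0.25, adjusted p = 0.00965). The count was 519 without dKO replicate 1, 1580 without dKO replicate 2 (795 higher and 785 lower), 835 without dKO_NICD replicate 1 (234 higher and 601 lower), 229 without dKO_NICD replicate 2, 2599 with DESeq2, 297 in a fit of only the groups compared and 1967 with all 14 libraries in 1 fit.

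The Notch and progenitor lists were higher by camera, and 9 lists were lower. Of 15 Notch pathway targets tested, 5 were higher and 0 lower (7 and 0 adjusted over the list alone). Adjusted p was 3.19e-05 by camera and 0.0841 with an estimated correlation. Of 20 stem and progenitor genes tested, 10 were higher and 0 lower (14 and 1 adjusted over the list alone). Adjusted p was 2.12e-08 by camera and 0.370 with an estimated correlation. Of 23 ILC2 and ILC precursor genes tested, 0 were higher and 9 lower (1 and 12 adjusted over the list alone). Adjusted p was 1.85e-08 by camera and 0.0841 with an estimated correlation. Of 13 ILC3 and lymphoid tissue inducer genes tested, 0 were higher and 6 lower (0 and 7 adjusted over the list alone). Adjusted p was 2.39e-05 by camera and 0.0841 with an estimated correlation. Of 20 NK and ILC1 genes tested, 1 were higher and 5 lower (1 and 10 adjusted over the list alone). Adjusted p was 3.95e-04 by camera and 0.304 with an estimated correlation. Tbx21 and Klrb1c fell (-2.23 ± 0.21 and -2.33 ± 0.25). Gzmb, at 866 ± 101 CPM in dKO and 1029.8 ± 102 CPM in dKO_NICD, was not called (0.25 ± 0.13, adjusted p = 0.276). Of 25 T-lineage specification genes tested, 2 were higher and 9 lower (5 and 13 adjusted over the list alone). Adjusted p was 0.00168 by camera and 0.297 with an estimated correlation. Zap70, a kinase of T cell receptor signalling, Ets1, a transcription factor, and Thy1, a surface protein of T cells, fell (-1.98 ± 0.15, -1.57 ± 0.14 and -2.36 ± 0.28). Of 23 cytokine and homing receptors tested, 1 were higher and 12 lower (2 and 15 adjusted over the list alone). Adjusted p was 4.22e-07 by camera and 0.0841 with an estimated correlation. Among them Il7r, the IL-7 receptor, fell from 192 ± 7.82 to 39.9 ± 2.15 CPM (-2.26 ± 0.10, adjusted p = 0.00126). Of 17 glycolysis genes tested, 0 were higher and 8 lower (1 and 9 adjusted over the list alone). Adjusted p was 4.48e-06 by camera and 0.410 with an estimated correlation. Slc16a3 and Pfkp were both lower (-2.04 ± 0.12 and -1.82 ± 0.10). Of 17 p53 target and BCL2 family genes tested, 1 were higher and 6 lower (1 and 11 adjusted over the list alone). Adjusted p was 2.05e-05 by camera and 0.0841 with an estimated correlation. Of 19 interferon response genes tested, 0 were higher and 2 lower (0 and 4 adjusted over the list alone). Adjusted p was 3.19e-05 by camera and 0.551 with an estimated correlation. Of 22 G2 and M phase genes tested, 0 were higher and 4 lower (0 and 5 adjusted over the list alone). Adjusted p was 5.44e-04 by camera and 0.551 with an estimated correlation. Cspg4, a surface proteoglycan, rose from 0.0360 ± 0.0509 to 16.2 ± 1.03 CPM (8.56 ± 0.95, adjusted p = 0.00785). Dct was at 347 and 44.5 CPM in the dKO_NICD libraries and 6.89 and 24.3 CPM in the dKO libraries.

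The difference from control in the group with active NOTCH1 was examined by comparing dKO_NICD with Cont. Gzmb and Klrc1 were above control, Rag1 and Ptcra were below it, and Heyl and Notch1, both of the Notch pathway, differed from it in opposite directions. Gzmb was at 1029.8 ± 102 CPM against 31.1 ± 4.12 CPM in Cont (5.05 ± 0.16, adjusted p = 2.40e-04). Klrc1 was higher as well (3.48 ± 0.31). Rag1 was at 2.31 ± 0.554 CPM against 201 ± 35.4 CPM (-6.44 ± 0.41, adjusted p = 0.00257). Il7r was lower (-1.44 ± 0.10). Heyl was higher than in Cont (3.69 ± 0.24, adjusted p = 0.00257), as was Cd22, an inhibitory receptor of B cells (7.24 ± 0.58). Ptcra (-9.35 ± 0.70, adjusted p = 0.00576) and Notch1 (-0.89 ± 0.11, adjusted p = 0.0147) were lower. Of 14137 genes, 529 passed, 358 higher and 171 lower in dKO_NICD, with Tcf12 (-3.78 ± 0.12) and Tcf3 (-1.42 ± 0.24, adjusted p = 0.0347) among the lower ones. Leaving out any 1 library of the 2 groups ended the call of Tcf3 (highest adjusted p = 0.221). Without Cont replicate 1 the count was 51, without Cont replicate 2 it was 62 and without dKO_NICD replicate 2 it was 298. Leaving out either Cont library ended the calls of Ptcra and Notch1 (highest adjusted p = 0.0776 and 0.121). DESeq2 called 1380 genes, and 947 passed with all 14 libraries in 1 fit.

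Among the lists, T-lineage genes were below Cont and NK and interferon genes above it. T-lineage specification genes had 1 higher and 16 lower of 25 tested (2 and 20 adjusted over the list alone). Adjusted p was 1.85e-15 by camera and 0.131 with an estimated correlation. NK and ILC1 genes had 13 higher and 0 lower of 20 tested (17 and 0 adjusted over the list alone). Adjusted p was 8.68e-15 by camera and 0.170 with an estimated correlation. Interferon response genes had 12 higher and 0 lower of 19 tested (18 and 0 adjusted over the list alone). Adjusted p was 2.58e-12 by camera and 0.372 with an estimated correlation. Stem and progenitor genes had 5 higher and 0 lower of 20 tested (13 and 0 adjusted over the list alone). Adjusted p was 9.28e-11 by camera and 0.372 with an estimated correlation. Mef2c and Meis1, transcription factors of blood stem cells, were higher by 1.64 ± 0.14 and 2.01 ± 0.19, and Lef1 was lower (-1.18 ± 0.11). Leaving out either Cont library ended these 3 calls (highest adjusted p = 0.0616, 0.0636 and 0.0730). Mast cell and basophil genes had 3 higher and 0 lower of 11 tested (8 and 0 adjusted over the list alone). Adjusted p was 3.92e-05 by camera and 0.372 with an estimated correlation. Gamma-delta T cell genes had 0 higher and 4 lower of 13 tested (1 and 7 adjusted over the list alone). Adjusted p was 2.35e-04 by camera and 0.372 with an estimated correlation. Camera also placed the myeloid, dendritic cell, and immediate early lists higher and the S phase, G2 and M phase, and ribosomal protein lists lower, with at most 3 members called in 1 direction each. Pax3, a transcription factor of the melanocyte lineage, was at 18.3 and 2.22 CPM in the dKO_NICD libraries and 0 in both Cont libraries, and Dct was at 2.46 and 0 CPM in Cont. The ILC2 and ILC precursor list, called in dKO versus Cont, was not called here, with 3 higher and 1 lower of 23 (5 and 1 adjusted over the list alone, camera adjusted p = 0.177). Glycolysis was not called either, with 0 higher and 0 lower of 17 (0 and 0 adjusted over the list alone, camera adjusted p = 0.0524). Whether these lists differ between the comparisons was tested by dKO_NICD versus dKO.

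The 2554 genes called in dKO versus Cont were followed into dKO_NICD. Rag1, Tcf12, Gzmb and Klrc1 were among 401 of them (15.7%) that were also called the same way in dKO_NICD versus Cont, where 18 were called the other way. Id2, Il2rb, Cxcr6, Ltb, Slc16a3 and Pfkp were among 816 (31.95%) that were called the opposite way in dKO_NICD versus dKO, where 24 were called the same way. The 4 tested Y-chromosome genes were among the 816, and calls that follow sex were not separated. Independent lists of these sizes would share 50.1 and 103.5 genes. These comparisons share libraries, so 20 data sets were simulated. With no group changed, the median number of calls per comparison was 0 to 0.5, so the median of 0 shared genes was fixed in either case. With dKO_NICD drawn at the dKO means, a median of 77.96% of the dKO calls was retained (range 76.3% to 78.8%) and 0 were called back. With dKO_NICD drawn at the Cont means, 0 were retained and 77.96% were called back (range 76.5% to 79.9%). Both observed shares lay between these extremes. The 2 sets of simulations had medians of 3193 and 3237 dKO versus Cont calls, against 2554 observed, so the extremes are no exact yardstick. The covariance of log2 fold changes was 1.20 for dKO and dKO_NICD versus Cont against 0.21 simulated without change, and -1.30 against -0.20 for dKO versus Cont and dKO_NICD versus dKO. Each part of a split of the controls would hold 1 library, so they were not split, and part of the excess over independent lists may come from the shared libraries. The 401 became 39 without Cont replicate 1, 47 without Cont replicate 2, 236 without dKO_NICD replicate 2 and 910 with DESeq2. The 816 became 186 and 173 without Cont replicates 1 and 2, 385 and 1243 without dKO replicates 1 and 2, 497 and 182 without dKO_NICD replicates 1 and 2, and 1755 with DESeq2.

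**Figure D3:**
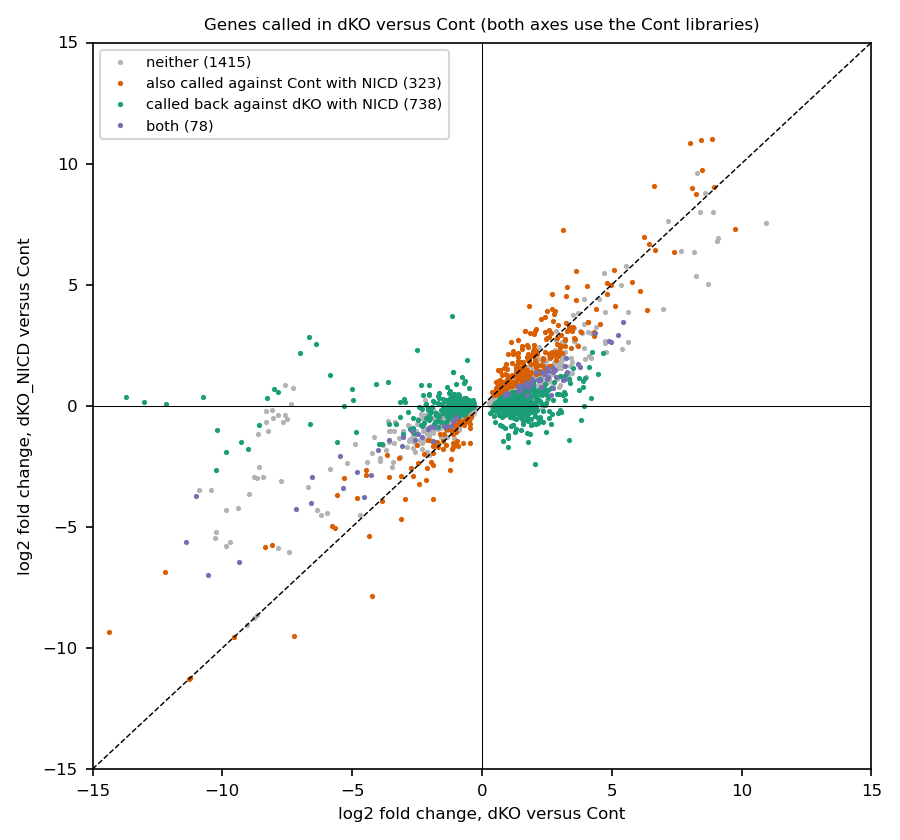
Log2 fold change in dKO_NICD versus Cont (vertical axis) against dKO versus Cont (horizontal axis) for the 2554 genes called in dKO versus Cont, 1 point per gene. Of these genes 323 were also called against Cont alone, 738 were called back against dKO alone, 78 met both and 1415 met neither, and both axes share the Cont libraries.

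Loss of E47 was examined in experiment 2 by comparing E47KO with B6. ETP without E47 had lower levels of Notch receptor, recombinase and T-lineage transcripts and higher levels of ILC2 transcripts. Notch1 fell from 349 ± 17.7 to 52.7 ± 4.65 CPM (-2.73 ± 0.11, adjusted p = 6.74e-05). Notch3 fell (-3.83 ± 0.38), as did Myc, a growth regulator downstream of Notch (-1.29 ± 0.12). Ptcra fell from 69.1 ± 7.27 to 0.171 ± 0.0371 CPM (-8.58 ± 0.38, adjusted p = 1.56e-04). Rag1 and Rag2, the recombinase pair, fell as well (-4.82 ± 0.28 and -3.42 ± 0.19). Ly6d, a surface marker of lymphoid progenitors with B-cell potential, fell from 26.9 ± 2.42 to 0.0241 ± 0.0341 CPM (-10.09 ± 0.50, adjusted p = 1.56e-04). Id3 fell (-3.09 ± 0.40) while Id2 rose (0.97 ± 0.09, adjusted p = 0.00120). Rora, a transcription factor of ILC2, rose from 92.6 ± 2.82 to 286 ± 7.85 CPM (1.63 ± 0.14, adjusted p = 9.50e-04). Higher as well were Zbtb16, the ILC precursor factor PLZF (1.41 ± 0.17), Gata3 (1.06 ± 0.10), Pdcd1, the receptor PD-1 (1.61 ± 0.13), and Arg1, arginase 1 of ILC2 (2.36 ± 0.26). Of 14114 genes tested, 1288 passed, 692 higher and 596 lower. Tcf3 was among the lower ones (-1.68 ± 0.14) while Tcf12 did not pass (-0.48 ± 0.14, adjusted p = 0.0686) but was called lower with DESeq2, in a fit of only the groups compared and with all 14 libraries in 1 fit. The count was 324 and 343 without B6 replicates 1 and 2, 621 and 401 without E47KO replicates 1 and 2, and 2068 with DESeq2.

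Innate lymphoid lists were higher and Notch and T-lineage lists lower in E47KO by camera. Of 23 ILC2 and ILC precursor genes tested, 14 were higher and 0 lower (14 and 0 adjusted over the list alone). Adjusted p was 3.51e-11 by camera and 0.182 with an estimated correlation. Of 20 NK and ILC1 genes tested, 11 were higher and 0 lower (14 and 0 adjusted over the list alone). Adjusted p was 9.20e-10 by camera and 0.244 with an estimated correlation. Of 13 ILC3 and lymphoid tissue inducer genes tested, 4 were higher and 1 lower (5 and 1 adjusted over the list alone). Adjusted p was 0.0159 by camera and 0.244 with an estimated correlation. Klrc1, Gzmb and the chemokine Ccl5 rose by 2.06 ± 0.17, 2.19 ± 0.19 and 2.06 ± 0.21. Of 11 mast cell and basophil genes tested, 6 were higher and 0 lower (7 and 0 adjusted over the list alone). Adjusted p was 1.97e-05 by camera and 0.244 with an estimated correlation. Among them were Hdc, which makes histamine (2.89 ± 0.29, adjusted p = 0.00211), and Fcer1a, a chain of the IgE receptor (6.54 ± 0.88, adjusted p = 0.00462). Of 15 Notch pathway targets tested, 1 were higher and 8 lower (1 and 9 adjusted over the list alone). Adjusted p was 6.27e-06 by camera and 0.184 with an estimated correlation. Of 24 T-lineage specification genes tested, 3 were higher and 10 lower (3 and 12 adjusted over the list alone). Adjusted p was 0.0146 by camera and 0.245 with an estimated correlation. Of 20 stem and progenitor genes tested, 2 were higher and 7 lower (2 and 9 adjusted over the list alone). Adjusted p was 0.0166 by camera and 0.335 with an estimated correlation. Lyl1 and Nfe2, transcription factors of early blood progenitors, were lower (-2.08 ± 0.25 and -1.67 ± 0.20). Of 19 interferon response genes tested, 0 were higher and 5 lower (0 and 13 adjusted over the list alone). Adjusted p was 7.05e-05 by camera and 0.335 with an estimated correlation. This direction is opposite to that in dKO versus Cont. Of 17 glycolysis genes tested, 7 were higher and 0 lower (12 and 1 adjusted over the list alone). Adjusted p was 6.27e-06 by camera and 0.275 with an estimated correlation. Of 23 cytokine and homing receptors tested, 10 were higher and 2 lower (14 and 5 adjusted over the list alone). Adjusted p was 0.00204 by camera and 0.245 with an estimated correlation. Of 15 erythroid genes tested, 3 were higher and 0 lower (8 and 0 adjusted over the list alone). Adjusted p was 6.27e-06 by camera and 0.275 with an estimated correlation. Camera also placed the myeloid, G2 and M phase, and p53 lists higher and the double-positive thymocyte, S phase, and ribosomal protein lists lower, with at most 3 members called in 1 direction each. Mzb1 and Spib, genes of B cells and plasmacytoid dendritic cells, fell (-5.97 ± 0.29 and -5.12 ± 0.57). Dct was at 37.8 and 4.05 CPM in the E47KO libraries and at 0 in both B6 libraries.

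The N1En deletion was examined by comparing N1Edel with B6. ETP with the deletion had lower Notch1 and T-lineage transcripts. Transcripts of dendritic and myeloid cells and of the MHC class II genes H2-Aa, Cd74 and Ciita were higher. Notch1 fell from 349 ± 17.7 to 25.4 ± 0.410 CPM (-3.78 ± 0.12, adjusted p = 1.27e-05). Ptcra fell from 69.1 ± 7.27 to 0.174 ± 0.107 CPM (-8.51 ± 0.38, adjusted p = 2.35e-04). Trib2, a Notch target, Lck, a kinase of T cell receptor signalling, Cd3g, a chain of the receptor complex, Rag1 and Rag2 fell (-1.72 ± 0.16, -1.01 ± 0.09, -1.32 ± 0.14, -2.29 ± 0.25 and -1.74 ± 0.18). H2-Aa, a chain of MHC class II, rose from 26.7 ± 1.17 to 535 ± 59.5 CPM (4.33 ± 0.20, adjusted p = 1.88e-04). Cd74, the invariant chain, and Ciita, the activator of class II transcription, rose as well (4.51 ± 0.23 and 4.90 ± 0.29). Irf8, a transcription factor of dendritic cells and monocytes, rose from 34.3 ± 5.52 to 412 ± 27.0 CPM (3.59 ± 0.26, adjusted p = 6.41e-04). So did Flt3, a cytokine receptor of progenitors (2.16 ± 0.17), Spi1, the transcription factor PU.1 (1.28 ± 0.14), and Prtn3, a granule protease (2.23 ± 0.18). Of 14114 genes, 698 passed, 398 higher and 300 lower, and Tcf3 was not among them (0.13 ± 0.14, adjusted p = 0.638). The count was 233 and 172 without B6 replicates 1 and 2, 202 and 132 without N1Edel replicates 1 and 2, 1518 with DESeq2 and 1647 in a fit of only the groups compared.

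Dendritic and myeloid lists were higher and Notch and T-lineage lists lower in N1Edel. Dendritic cell genes had 8 higher and 0 lower of 15 tested (10 and 1 adjusted over the list alone). Adjusted p was 2.26e-07 by camera and 0.214 with an estimated correlation. Myeloid genes had 7 higher and 0 lower of 22 tested (12 and 0 adjusted over the list alone). Adjusted p was 1.48e-08 by camera and 0.0451 with an estimated correlation. Notch pathway targets had 0 higher and 9 lower of 15 tested (0 and 12 adjusted over the list alone). Adjusted p was 1.42e-11 by camera and 0.0451 with an estimated correlation. T-lineage specification genes had 0 higher and 13 lower of 24 tested (2 and 15 adjusted over the list alone). Adjusted p was 4.61e-11 by camera and 0.0451 with an estimated correlation. The myeloid, Notch and T-lineage lists were the 3 that also passed with an estimated correlation. Mast cell and basophil genes had 3 higher and 0 lower of 11 tested (8 and 2 adjusted over the list alone). Adjusted p was 0.00197 by camera and 0.341 with an estimated correlation. Glycolysis genes had 3 higher and 0 lower of 17 tested (4 and 1 adjusted over the list alone). Adjusted p was 0.0109 by camera and 0.591 with an estimated correlation. Ribosomal protein genes had 1 higher and 0 lower of 84 tested (0 and 0 adjusted over the list alone). Adjusted p was 4.31e-06 by camera and 0.563 with an estimated correlation. Interferon response genes had 0 higher and 1 lower of 19 tested (1 and 6 adjusted over the list alone). Adjusted p was 2.54e-04 by camera and 0.526 with an estimated correlation. The S phase list was lower by camera with 1 called member. The innate lymphoid lists were not called. ILC2 and ILC precursor genes had 3 higher and 1 lower of 23 (5 and 1 adjusted over the list alone, camera adjusted p = 0.654). ILC3 genes had 2 higher and 0 lower of 13 (2 and 1 adjusted over the list alone, camera adjusted p = 0.189). NK and ILC1 genes had 4 higher and 0 lower of 20 (6 and 2 adjusted over the list alone, camera adjusted p = 0.132), although Lta and Ccl5 rose (2.85 ± 0.22 and 3.86 ± 0.23). Both N1Edel libraries had Y-chromosome genes at 0 CPM, against 62.3 and 66.8 CPM in the B6 libraries. Dct was at 0 and 35.8 CPM in the N1Edel libraries and at 0 in both B6 libraries.

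The effect of both changes together was examined by comparing N1Edel_E47KO with B6. ETP with both changes had lower Notch pathway and T-lineage transcripts and higher ILC2 and NK transcripts. Ptcra and Ly6d were at 0 in both N1Edel_E47KO libraries, at least 1187-fold and 463-fold lower than in B6 (adjusted p = 6.24e-05 and 1.45e-04). Notch1 fell from 349 ± 17.7 to 37.0 ± 0.583 CPM (-3.24 ± 0.11, adjusted p = 1.60e-05). Notch3, the Notch target Hes5, Rag1, Rag2 and the T cell glycoprotein Cd5 were lower (-4.62 ± 0.39, -6.01 ± 0.66, -7.25 ± 0.33, -4.35 ± 0.20 and -5.66 ± 0.76). Id2 rose from 523 ± 11.1 to 1135 ± 59.5 CPM (1.12 ± 0.09, adjusted p = 6.48e-04). Rora, Zbtb16, Gata3 and Arg1 rose as well (1.43 ± 0.14, 1.36 ± 0.17, 1.07 ± 0.10 and 2.62 ± 0.26). Gzmb, Ccl5, the receptor gene Klrk1 (NKG2D) and Ncr1 (NKp46) rose by 2.63 ± 0.19, 3.55 ± 0.22, 2.21 ± 0.20 and 3.57 ± 0.43. Hlf, a transcription factor of stem cells, fell (-2.03 ± 0.20, adjusted p = 0.00133), and Bcl2, a survival factor, rose (1.10 ± 0.13, adjusted p = 0.00247). Of 14114 genes, 1553 passed, 884 higher and 669 lower, with Tcf3 (-1.53 ± 0.14) and Id3 (-2.98 ± 0.40) among the lower ones. The count was 611 and 408 without B6 replicates 1 and 2, 2206 without N1Edel_E47KO replicate 1 (1063 higher and 1143 lower), 2364 with DESeq2 and 526 in a fit of only the groups compared.

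The libraries of N1Edel_E47KO stood further apart than those of the other groups, with a chi-square per gene of 83.9 against 19.4 to 47.4. Their Spearman correlation was 0.970, against 0.978 to 0.9895 in the other groups. The 45S rRNA took 0.697% and 0.799% of their counts, against 1.496% to 1.98% in the other libraries of experiment 2. Of 15 Notch pathway targets tested, 0 were higher and 9 lower (1 and 11 adjusted over the list alone). Adjusted p was 1.75e-08 by camera and 0.166 with an estimated correlation. Of 24 T-lineage specification genes tested, 4 were higher and 13 lower (4 and 13 adjusted over the list alone). Adjusted p was 4.71e-05 by camera and 0.245 with an estimated correlation. Of 23 ILC2 and ILC precursor genes tested, 13 were higher and 0 lower (14 and 0 adjusted over the list alone). Adjusted p was 3.39e-07 by camera and 0.216 with an estimated correlation. Of 20 NK and ILC1 genes tested, 14 were higher and 1 lower (17 and 1 adjusted over the list alone). Adjusted p was 8.45e-11 by camera and 0.314 with an estimated correlation. Of 13 ILC3 and lymphoid tissue inducer genes tested, 4 were higher and 1 lower (4 and 2 adjusted over the list alone). Adjusted p was 0.0495 by camera and 0.314 with an estimated correlation. With size factors by the DESeq2 method this list was not called (adjusted p = 0.0558). Of 11 mast cell and basophil genes tested, 6 were higher and 0 lower (8 and 1 adjusted over the list alone). Adjusted p was 3.96e-04 by camera and 0.314 with an estimated correlation. Of 17 glycolysis genes tested, 5 were higher and 1 lower (7 and 1 adjusted over the list alone). Adjusted p was 9.08e-04 by camera and 0.410 with an estimated correlation. Of 23 cytokine and homing receptors tested, 9 were higher and 4 lower (11 and 5 adjusted over the list alone). Adjusted p was 0.0406 by camera and 0.410 with an estimated correlation. Of 84 ribosomal protein genes tested, 0 were higher and 12 lower (0 and 15 adjusted over the list alone). Adjusted p was 3.24e-08 by camera and 0.410 with an estimated correlation. The G2 and M phase list was higher by camera, with 0 called members. Dct was at 138 and 33.6 CPM in the N1Edel_E47KO libraries and at 0 in both B6 libraries.

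The N1En deletion on top of E47 loss was examined by comparing N1Edel_E47KO with E47KO, where few genes passed. Tdg, a DNA glycosylase of base excision repair, fell from 111 ± 0.336 to 8.25 ± 0.277 CPM (-3.76 ± 0.15, adjusted p = 4.07e-05). Tdg-ps2 fell with it (-3.93 ± 0.15). Its coordinates overlap those of Tdg (chromosome 10, 82092587 to 82113022 and 82092583 to 82113544), so these 2 calls are of 1 locus. Akr1c12 and Akr1c13, similar genes of aldo-keto reductases, fell (-2.32 ± 0.21 and -1.71 ± 0.14). So did Hlf (-1.92 ± 0.20, adjusted p = 0.0251) and the 45S rRNA (1.55% and 1.496% of counts in E47KO, 0.697% and 0.799% with both changes). The splicing helicase gene Dhx38 rose (0.95 ± 0.11, adjusted p = 0.0471). The levels of Rag1 (6.07 ± 2.40 and 1.11 ± 0.103 CPM) and Notch1 (52.7 ± 4.65 and 37.0 ± 0.583 CPM) were not called (-2.43 ± 0.30, adjusted p = 0.0553 and -0.51 ± 0.11, adjusted p = 0.107). Rag1 was called lower with DESeq2, without a filter on low counts and with all 14 libraries in 1 fit. Its adjusted p was 0.0115 without E47KO replicate 1 and 0.01125 without N1Edel_E47KO replicate 1. Notch1 was called with DESeq2. The 7 genes, 1 higher and 6 lower, compare with 2131 at an unadjusted p under 0.05 by edgeR and 688 called by DESeq2 (407 higher and 281 lower). With all 14 libraries in 1 fit, 34 were higher and 26 lower. The count was 4 without E47KO replicate 2, 1010 without N1Edel_E47KO replicate 1, 59 without N1Edel_E47KO replicate 2, 60 with all 14 libraries in 1 fit, and 69 without a filter on low counts (33 higher and 36 lower). Leaving out either E47KO library ended the calls of Hlf and Dhx38 (highest adjusted p = 0.148 and 0.303), and Akr1c12, Akr1c13, Hlf and Dhx38 were not called in a fit of only the groups compared. Interferon response genes had 0 higher and 0 lower of 19 tested (13 and 0 adjusted over the list alone). Adjusted p was 8.65e-09 by camera and 0.606 with an estimated correlation. Among the members, Ifit3 had 3.11 ± 0.46 (adjusted p = 0.0684, and 0.00178 without N1Edel_E47KO replicate 1). Ifit3 was called with DESeq2 and without a filter. T-lineage specification genes had 0 higher and 0 lower of 24 tested (0 and 8 adjusted over the list alone). Adjusted p was 1.78e-04 by camera and 0.578 with an estimated correlation. Notch pathway targets had 0 higher and 0 lower of 15 tested (0 and 5 adjusted over the list alone). Adjusted p was 0.00343 by camera and 0.578 with an estimated correlation. NK and ILC1 genes had 0 higher and 0 lower of 20 tested (3 and 1 adjusted over the list alone). Adjusted p was 0.00101 by camera and 0.635 with an estimated correlation. Camera also placed dendritic cell genes higher and erythroid, glycolysis and ribosomal protein genes lower, with 0 called members each. Dct was at 37.8 and 4.05 CPM in E47KO and 138 and 33.6 CPM with both changes.

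Loss of E47 on top of the N1En deletion was examined by comparing N1Edel_E47KO with N1Edel. Y-chromosome genes were at 86.8 and 249.8 CPM in N1Edel_E47KO and at 0 CPM in both N1Edel libraries, and effects of sex were not separated. H2-Aa, Irf8 and Prtn3, which were higher in N1Edel than in B6, were lower with both changes, and Rora, Arg1 and Klrc1 were higher. H2-Aa fell from 535 ± 59.5 to 71.7 ± 1.39 CPM (-2.90 ± 0.19, adjusted p = 7.29e-04). Irf8 and Prtn3 fell as well (-2.35 ± 0.24 and -2.45 ± 0.18). Ly6d, at 53.04 ± 4.35 CPM in N1Edel, was at 0 with both changes, at least 911-fold lower (adjusted p = 2.30e-04). Mzb1, Rag1 and Rag2 fell (-5.43 ± 0.29, -4.96 ± 0.30 and -2.61 ± 0.19). Rora, Arg1 and Klrc1 rose (1.45 ± 0.14, 2.95 ± 0.26 and 2.12 ± 0.17). Of 14114 genes, 513 passed, 230 higher and 283 lower, with Tcf3 (-1.66 ± 0.14) and Tdg-ps2 (-3.81 ± 0.15) among the lower ones. With all 14 libraries in 1 fit, 289 were higher and 264 lower, and in a fit of only the groups compared 33 and 83. The count was 64 and 85 without N1Edel replicates 1 and 2, 2098 without N1Edel_E47KO replicate 1, 1356 with DESeq2 and 116 in a fit of only the groups compared. Of 15 dendritic cell genes tested, 0 were higher and 7 lower (1 and 10 adjusted over the list alone). Adjusted p was 1.53e-07 by camera and 0.272 with an estimated correlation. Of 22 myeloid genes tested, 0 were higher and 6 lower (1 and 13 adjusted over the list alone). Adjusted p was 2.12e-07 by camera and 0.128 with an estimated correlation. Of 20 NK and ILC1 genes tested, 12 were higher and 0 lower (13 and 0 adjusted over the list alone). Adjusted p was 1.41e-08 by camera and 0.341 with an estimated correlation. Of 23 ILC2 and ILC precursor genes tested, 7 were higher and 0 lower (17 and 0 adjusted over the list alone). Adjusted p was 2.73e-08 by camera and 0.170 with an estimated correlation. Of 19 interferon response genes tested, 2 were higher and 0 lower (8 and 1 adjusted over the list alone). Adjusted p was 3.08e-05 by camera and 0.527 with an estimated correlation. Of 20 stem and progenitor genes tested, 1 were higher and 3 lower (2 and 6 adjusted over the list alone). Adjusted p was 0.0137 by camera and 0.527 with an estimated correlation. Of 12 B-lineage genes tested, 0 were higher and 1 lower (0 and 2 adjusted over the list alone). Adjusted p was 0.0165 by camera and 0.272 with an estimated correlation. Of 23 cytokine and homing receptors tested, 6 were higher and 1 lower (12 and 7 adjusted over the list alone). Adjusted p was 0.0140 by camera and 0.520 with an estimated correlation. Of 84 ribosomal protein genes tested, 0 were higher and 11 lower (0 and 60 adjusted over the list alone). Adjusted p was 7.49e-24 by camera and 0.341 with an estimated correlation. The 45S rRNA took 1.64% and 1.62% of the counts of the N1Edel libraries against 0.697% and 0.799% with both changes. Dct was at 0 and 35.8 CPM in N1Edel and 138 and 33.6 CPM with both changes. The G2 and M phase list was higher by camera, with 0 called members.

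Whether the effect of E47 loss differs with and without the N1En deletion was tested by the interaction of the changes. Of the 4 tested Y-chromosome genes 2 passed, and effects of sex were not separated. Notch1 had the smallest p, with an interaction of 3.27 ± 0.15 (adjusted p = 3.27e-04). Its levels were 349 ± 17.7 CPM in B6, 52.7 ± 4.65 CPM in E47KO, 25.4 ± 0.410 CPM in N1Edel and 37.0 ± 0.583 CPM in N1Edel_E47KO. H2-Aa had an interaction of -4.07 ± 0.26 (not called with all 14 libraries in 1 fit), at 26.7 ± 1.17, 60.0 ± 17.0, 535 ± 59.5 and 71.7 ± 1.39 CPM in the same groups. Prtn3 had -2.70 ± 0.25 (adjusted p = 0.00507). Tdg and Tdg-ps2 had -3.51 ± 0.19 and -3.67 ± 0.19, and Tdg was at 123 ± 4.57, 111 ± 0.336, 103 ± 16.4 and 8.25 ± 0.277 CPM. Rag1, Gata3 and Id3 did not pass (-0.14 ± 0.38, adjusted p = 0.877, -0.09 ± 0.14, adjusted p = 0.789 and 2.55 ± 0.55, adjusted p = 0.0802), and Rag1 had 0.31 without E47KO replicate 2 and 0.02 without N1Edel replicate 1. Id3 was called with DESeq2 and without a filter, and its adjusted p was 0.0289 and 0.0139 without N1Edel_E47KO replicates 1 and 2. Of 14114 genes, 159 passed, 51 higher and 108 lower, against 2319 at an unadjusted p under 0.05 by edgeR. The count was 48 and 48 without B6 replicates 1 and 2, 53 and 31 without E47KO replicates 1 and 2, 39 and 22 without N1Edel replicates 1 and 2, 1462 without N1Edel_E47KO replicate 1, 724 with DESeq2, 107 with all 14 libraries in 1 fit (52 higher and 55 lower) and 225 without a filter (78 higher and 147 lower). Interferon response genes had 2 higher and 0 lower of 19 tested (17 and 0 adjusted over the list alone). Adjusted p was 1.31e-11 by camera and 0.238 with an estimated correlation. Notch pathway targets had 2 higher and 0 lower of 15 tested (6 and 0 adjusted over the list alone). Adjusted p was 4.94e-05 by camera and 0.224 with an estimated correlation. T-lineage specification genes had 3 higher and 0 lower of 24 tested (7 and 0 adjusted over the list alone). Adjusted p was 0.00131 by camera and 0.238 with an estimated correlation. Myeloid genes had 0 higher and 3 lower of 22 tested (0 and 11 adjusted over the list alone). Adjusted p was 9.21e-10 by camera and 0.0773 with an estimated correlation. Dendritic cell genes had 0 higher and 5 lower of 15 tested (2 and 6 adjusted over the list alone). Adjusted p was 2.67e-04 by camera and 0.238 with an estimated correlation. Mast cell and basophil genes had 0 higher and 2 lower of 11 tested (0 and 5 adjusted over the list alone). Adjusted p was 1.73e-04 by camera and 0.238 with an estimated correlation. Glycolysis genes had 0 higher and 0 lower of 17 tested (0 and 6 adjusted over the list alone). Adjusted p was 3.52e-04 by camera and 0.422 with an estimated correlation. Erythroid, p53 and ribosomal protein genes were lower by camera with 0 called members each. S phase genes had 0 higher and 0 lower of 21 tested (1 and 0 adjusted over the list alone). Adjusted p was 0.00441 by camera and 0.238 with an estimated correlation. Of 207 list tests, 34 had a median, mean and camera direction that differed in sign, and this was the 1 called among them.

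Calls were compared across the 2 experiments, which share no library. Ptcra, Rag1 and Mzb1 were lower in dKO versus Cont and in E47KO versus B6, with log2 fold changes of -9.35 and -4.82 for Rag1 and -7.16 and -5.97 for Mzb1. Of 13670 genes tested in both experiments, dKO versus Cont shared 724 same-direction calls with E47KO versus B6 (120.0 for independent lists, 27 opposite). The Spearman correlation of log2 fold changes across genes was 0.502. In the same order, values were 806, 146.1, 19 and 0.427 for N1Edel_E47KO versus B6, and 258, 64.4, 36 and 0.293 for N1Edel versus B6. The 4 tested Y-chromosome genes, lower in both, were among the 258, and sex was not separated. Genes are not independent replicates, and the difference between these overlaps was not tested. The overlaps with E47KO, N1Edel_E47KO and N1Edel were 306, 345 and 111 without Cont replicate 1, 241, 264 and 93 without Cont replicate 2, 221, 375 and 91 without B6 replicate 1, and 220, 271 and 62 without B6 replicate 2. The first was 378 and 276 without E47KO replicates 1 and 2, the last 91 and 51 without N1Edel replicates 1 and 2, and with DESeq2 the 3 were 1216, 1276 and 609.

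Within experiment 2 the comparisons share the B6 libraries. Ptcra, Notch1, Rag1 and Rag2 were lower in all 3 mutant groups, with log2 fold changes for Rag2 of -3.42 in E47KO, -1.74 in N1Edel and -4.35 in N1Edel_E47KO. E47KO and N1Edel shared 321 calls in the same direction (32.2 for independent lists, 12 opposite). E47KO and N1Edel_E47KO shared 864 (71.6 for independent lists, 0 opposite). N1Edel and N1Edel_E47KO shared 412 (39.1 for independent lists, 5 opposite). Unchanged groups simulated 20 times against these controls had a median of 0 to 1 calls per comparison, so their median of 0 shared calls was fixed. It does not show how far shared libraries raise the overlap of real calls. The covariance of log2 fold changes was 0.93, 1.23 and 1.06 for the 3 pairs, against 0.15 simulated for each. Each part of a split of the controls would hold 1 library, so they were not split, and part of the excess over independent lists may come from the shared B6 libraries. The 3 overlaps were 88, 260 and 140 without B6 replicate 1, and 65, 224 and 88 without B6 replicate 2. Without E47KO replicates 1 and 2 the first was 194 and 154 and the second 476 and 353. Without N1Edel replicates 1 and 2 the first was 118 and 76 and the third 152 and 97. The third was 830 without N1Edel_E47KO replicate 2. With DESeq2 they were 685, 1334 and 844.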

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

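Of the tests in this part, those of mature macrophages and neutrophils, of sex, of a library batch and of a segment around Tcf3 were chosen after the result was seen, and that of dendritic cell genes before. The effect of E47 loss differed with the N1En deletion for 159 genes in the test of the interaction. Notch1 had the smallest p, with a log2 difference of 3.27. It was lower in E47KO than in B6 (-2.73 ± 0.11), and higher in N1Edel_E47KO than in N1Edel (0.54 ± 0.11, adjusted p = 0.0346). That last call ended without N1Edel replicates 1 and 2 (adjusted p = 0.247 and 0.164), without N1Edel_E47KO replicate 2 (adjusted p = 0.0610) and in a fit of only the groups compared (adjusted p = 0.197). Tdg and Tdg-ps2 had -3.51 and -3.67. H2-Aa, Cd74 and H2-Eb1, genes of MHC class II, had -4.07, -3.83 and -3.83, and Cst3, a protease inhibitor of dendritic cells, had -2.67. Csf2rb, a chain of the IL-3 and GM-CSF receptors, had -2.71. It was at 9.73 ± 1.16 CPM in B6, 49.2 ± 2.14 in E47KO, 45.5 ± 0.364 in N1Edel and 35.1 ± 5.17 in N1Edel_E47KO. H2-Aa, Cd74, H2-Eb1 and Csf2rb were not called with all 14 libraries in 1 fit (adjusted p = 0.0827, 0.120, 0.109 and 0.0624).

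H2-Aa, Cd74, H2-Eb1 and Cst3 were highest in N1Edel, where the 15 higher members of the dendritic and myeloid lists had a median log2 fold change of 3.59 against B6. Genes of mature macrophages and neutrophils had a median of 0.890 over 14 tested (0 called), with Lyz2 at 20.2 and 21.6 CPM in B6 and 16.5 and 29.4 CPM in N1Edel, and C1qa at 14.4 and 7.59 CPM in B6 and 10.7 and 32.2 CPM in N1Edel, which leaves those cells open, since 10 of the 16 were at 1 CPM or more in both B6 libraries and would hide a small share. In dKO versus Cont, groups that also differ in Y-chromosome genes, 13 tested members had a median of 0.469 (upper quartile 1.52). This does not decide on sex as the cause, because these groups differ in Tcf3 and Tcf12 too. Dendritic cell genes were lower where E47 was lost on top of the N1En deletion (0 higher and 7 lower of 15). The members were also chosen as higher in N1Edel. Dendritic cell genes not looked at before had a median of 1.95 over 15 tested (7 called higher), with Plbd1 at 13.3 and 12.1 CPM in B6 and 187 and 241 CPM in N1Edel and Ppt1 at 229 and 265 CPM in B6 and 371 and 349 CPM in N1Edel, although 12 of the 15 were at 1 CPM or more in both B6 libraries. A candidate explanation is that dendritic cells or precursors entered the sort despite its exclusion of CD11c+ and CD11b+ cells, and expression of these genes by N1Edel ETP themselves stays open, since bulk counts do not separate these.

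Tdg was low in both N1Edel_E47KO libraries (8.45 and 8.06 CPM) and in all of experiment 1, with 8.78 and 8.80 CPM in Cont, against 126 and 119 CPM in B6. A library or sequencing batch shared by these 8 libraries that moves many genes by over 1 log2 unit is argued against. Apart from Tdg and Tdg-ps2, 0 genes separated them from the other 6 by that much, where Tdg did so by 3.27. Smaller batch effects and a batch of N1Edel_E47KO alone were not tested. The 45S rRNA took 0.697% and 0.799% of the counts of N1Edel_E47KO, against 1.496% to 1.98% in the other libraries of experiment 2. Tdg lies 2.22 Mb from Tcf3, so a segment that came with a Tcf3 allele might differ, although E47KO had Tdg at 111 and 112 CPM. Within 5 Mb of Tcf3, 35 of 197 genes had an unadjusted p under 0.05 in N1Edel_E47KO versus E47KO (17.8%, against 15.1% elsewhere), a ratio of 1.18 with an upper 95% bound of 1.58, which leaves such a segment open. No biological explanation was tested.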

How the results depend on the processing

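The settings below were all planned. The text describes 160 pairs of a gene and a comparison, and 146 were called. Of these, 131 stayed called under every alternative run, and 137 under every alternative that used all libraries. Leaving out 1 library ended 9 of the calls. Because genes with stable calls were preferred, these shares do not apply to all calls. No described gene that was called turned its direction. Of those not called, Hes1, Dtx1 and Bcl11b in dKO versus Cont, Hes1 in dKO_NICD versus dKO and Rag1 in the interaction did so in a fit with 1 library left out.

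Size factors by the DESeq2 method moved no count by more than 1.5 times. In the simulated data DESeq2 itself called 34 to 65 unchanged genes per comparison, against 1 to 14 by edgeR. With DESeq2 the counts were 2599 for dKO_NICD versus dKO, 1380 for dKO_NICD versus Cont, 2068 for E47KO versus B6, 1518 for N1Edel versus B6, 2364 for N1Edel_E47KO versus B6, 688 for N1Edel_E47KO versus E47KO, 1356 for N1Edel_E47KO versus N1Edel and 724 for the interaction. The shared calls with DESeq2 were 910 for dKO and dKO_NICD versus Cont, 1755 for the calls opposite in dKO_NICD versus dKO, 1276, 1216 and 609 for dKO versus Cont with N1Edel_E47KO, E47KO and N1Edel, and 685, 1334 and 844 for E47KO with N1Edel, E47KO with N1Edel_E47KO and N1Edel with N1Edel_E47KO. In a fit of only the groups compared, with fewer libraries to estimate the spread, the counts were 297 for dKO_NICD versus dKO, 1647 for N1Edel versus B6, 526 for N1Edel_E47KO versus B6 and 116 for N1Edel_E47KO versus N1Edel. With all 14 libraries in 1 fit they were 1967 for dKO_NICD versus dKO, 947 for dKO_NICD versus Cont and 60 for N1Edel_E47KO versus E47KO, and the interaction had 52 higher and 55 lower. Without a filter N1Edel_E47KO versus E47KO had 69. The other counts run under these settings moved by at most 1.5 times, and the cause was not tested. Shared calls were not counted in a fit of only the groups compared or with all 14 libraries in 1 fit, nor the interaction in the former.

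The labels do not say that replicate numbers pair libraries. Replicate differences correlated between groups at -0.0188 to 0.0202 across genes in experiment 1 and at -0.181 to 0.0458 in experiment 2. With the replicate number as a replicate block, which leaves fewer degrees of freedom, the counts were 425 for N1Edel versus B6, 257 for N1Edel_E47KO versus N1Edel, 73 for the interaction, and 161, 208 and 263 for the overlaps of dKO with N1Edel, E47KO with N1Edel and N1Edel with N1Edel_E47KO. With the block, 3 of the 146 described calls were not called. These were Notch1 in N1Edel_E47KO versus N1Edel, and Hlf and Dhx38 in N1Edel_E47KO versus E47KO. Camera called 13 lists instead of 11 in dKO versus Cont (with mast cell and basophil and erythroid) and 12 instead of 11 in dKO_NICD versus dKO (with gamma-delta T cell). It called 11 instead of 12 in dKO_NICD versus Cont (without S phase) and 9 instead of 10 in N1Edel_E47KO versus B6 (without ILC3). The same number of lists was called in the other 5 comparisons.

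With 1 library left out, counts ranged from 436 to 2518 for dKO versus Cont, 229 to 1580 for dKO_NICD versus dKO, 51 to 475 for dKO_NICD versus Cont, 324 to 621 for E47KO versus B6, 132 to 233 for N1Edel versus B6, and 408 to 2206 for N1Edel_E47KO versus B6. They ranged from 4 to 1010 for N1Edel_E47KO versus E47KO, 64 to 2098 for N1Edel_E47KO versus N1Edel and 22 to 1462 for the interaction. Shared calls ranged from 39 to 442 for dKO and dKO_NICD versus Cont, 173 to 1243 for the calls opposite in dKO_NICD versus dKO, 264 to 863, 220 to 706 and 51 to 238 for dKO versus Cont with N1Edel_E47KO, E47KO and N1Edel, and 65 to 194, 224 to 1044 and 88 to 830 within experiment 2. Fewer libraries lower the power, and the cause of the rises without N1Edel_E47KO replicate 1 was not tested. With an estimated correlation between genes, 3 lists passed in N1Edel versus B6 and 0 in each of the other 8 comparisons. A higher correlation does not account for this in every list. Notch pathway targets and cytokine and homing receptors in dKO versus Cont had estimates of -0.0396 and -0.0079, below the preset value. Their unadjusted camera p still rose, from 5.30e-05 to 0.0229 and from 1.48e-05 to 0.017. Interferon response genes had an estimate of 0.864. The setting with an estimated correlation also uses the residual degrees of freedom, 3 in experiment 1 and 4 in experiment 2. The same statistic then gives a larger p, so a list that does not pass there is no evidence of correlated genes. How far each part raised p was not tested. The adjusted p by fry was 0.00209 for each of the first 2 lists and 0.0502 for interferon response. Depth limited genes near the floor of 3 counts per group.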

Other observations

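Of the tests in this part, that of melanocyte genes not looked at before was chosen before its result was seen, and the count of groups with unlike libraries and the sign tests after. Dct was at 2.46 and 0 CPM in Cont, 6.89 and 24.3 in dKO, 347 and 44.5 in dKO_NICD, 0 and 0 in B6, 37.8 and 4.05 in E47KO, 0 and 35.8 in N1Edel and 138 and 33.6 in N1Edel_E47KO.

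In 4 groups Dct was at 10 CPM or more in 1 library and over 4 times lower in the other, which argues against a cause in genotype alone. Of 8 melanocyte genes not looked at before, the median Spearman correlation with Dct across the 14 libraries was 0.902 (permutation p = 1e-05, the smallest that 100000 permutations can give), and the median Pearson correlation of log2(CPM + 1) was 0.812 (permutation p = 2e-05). Without dKO_NICD replicate 1 and N1Edel_E47KO replicate 1 the medians were 0.838 and 0.699, and they were 0.893 and 0.881 in experiment 1 and 0.9098 and 0.840 in experiment 2. Of the 8 genes, 3 were at 1 CPM or more in both B6 libraries, and Pmel was at 127 and 18.1 CPM in dKO_NICD. Melanoblasts, which carry KIT and none of the excluded markers, may have entered the gate in some libraries, and of the 15 melanoblast genes 3 were called higher in dKO_NICD versus Cont, 1 in dKO versus Cont and 0 lower.

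Hes1 and Nrarp, both targets of Notch, differed between the libraries of a group in the same direction in 7 of 7 groups (exact sign test, two-sided, p = 0.0156, 0.0469 adjusted over 3 tests). Hes1 and Dtx1 did so in 5 of 7 groups (exact p = 0.453, 0.680 adjusted), and Hes1 and immediate early genes in 4 of 7 (exact p = 1, 1 adjusted). Hes1 was at 30.1 and 70.9 CPM in Cont, 15.3 and 154 CPM in B6, 48.3 and 9.01 CPM in dKO_NICD and 44.3 and 4.58 CPM in N1Edel_E47KO.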
